A study of Mus musculus with 14 samples.

How the data were processed

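RNA was sequenced from the cerebral cortex of both hemispheres in 14 mouse samples of 3 groups: 4 sham samples, 5 samples at 2 d and 5 samples at 7 d after a cerebral venous sinus thrombosis (CVST) was induced, a clot in the veins that drain the brain. Per the labels, total RNA was extracted with Trizol and made into libraries with the NEBNext Ultra RNA kit. The labels do not give the collection time of the sham samples, nor the sex or age of the mice. They number the samples within each group without saying outright that each is a separate animal. The samples are called animals below, and the p of gene tests and of the exact permutation measure the spread between samples. Camera at a preset correlation treats the genes of a list as nearly independent, so its p does not.

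The authors deposited a table of read counts per gene and a table of FPKM values (fragments scaled to transcript length in kilobases and to library size) for the same 14 samples. Per the submitters' processing notes, reads were processed with fastp, HISAT2 and DESeq2 1.16.1 on the mouse build mm39. The versions of fastp and HISAT2, the counting tool and the annotation release are not given in the sources used here. The deposited counts were whole numbers, and the deposited FPKM values were proportional to count over gene length within a few percent. The count table held 55894 entries, of which 55359 carried an Ensembl gene. The remaining 535 were loci of an assembled transcriptome without an Ensembl gene. They held 0.203% to 0.278% of the counts of a sample and were left out of the comparisons, since they have no gene identity. Genes are given by the symbols of the deposited table. Positions are not given, because an annotation of build mm39 was not used here.

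Gene counts summed to 14.7 to 20.8 M per sample (M for mega; mean 17.6 M, SD 1.72, n = 14). TMM factors lay between 0.962 and 1.04. Counting error was a small part of the spread: between replicates the lowest chi-square per degree of freedom was 7.76, and the biological coefficient of variation was 0.218. PCR reads without molecular identifiers are not independent molecules, so counting intervals and floors cover counting error only. Where all sham libraries held 0 counts of a gene, the fold was taken against a floor of 3 counts over the 4 sham libraries (0.0406 CPM). Where they held 1 to 3 counts, a ratio of pooled CPM is given with its exact binomial interval at a confidence level of 0.95.

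Groups, the 3 comparisons (CVST 2 d against sham, CVST 7 d against sham, CVST 7 d against CVST 2 d), tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. All 14 samples were fitted together in edgeR 4.0.16 under R 4.3.3, with group means, TMM scaling and genes kept by filterByExpr, which left 16918 genes. Differences were tested with edgeR's quasi-likelihood test, 2-sided, with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are log2 values with the standard error (SE) of the fit, and levels are CPM, counts scaled to library size, with TMM factors, as mean and SD per group. Log2 CPM values used a prior count of 2. For the 2 comparisons with sham, genes were also grouped by time. Early genes were called at 2 d against sham and went back the other way between 2 d and 7 d. Sustained genes were called at both times in the same direction without a call between the times. Late genes were called at 7 d against sham and in the same direction between the times.

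Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 37 lists of each comparison. Each was also tested with an estimated correlation, with fry, and with a 2-sided exact permutation of a score per animal, the mean log2 CPM of the list. Scores are given relative to the mean of the sham animals. The smallest p that 4 against 5 or 5 against 5 animals allow is 0.00794. The lists were microglia in 2 states (homeostatic; disease-associated and lysosomal), monocytes and macrophages, neutrophils, lymphocytes, reactive astrocytes, homeostatic astrocytes, oligodendrocytes and myelin, oligodendrocyte precursors, blood-brain barrier endothelium, activated endothelium and haemostasis, mural cells, fibroblasts and extracellular matrix, excitatory cortical neurons, inhibitory interneurons, synaptic transmission, neuronal ion channels, immediate early genes, chemokines and cytokines, complement, interferon response, antigen presentation, pattern recognition and inflammasome, haem and iron handling, antioxidant and ferroptosis genes, hypoxia and glycolysis, cell cycle, p53 and apoptosis, heat shock and unfolded protein response, cholesterol biosynthesis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, red cells and platelets, choroid plexus, striatum, hippocampus and thalamus. For each list the calls over all genes and those adjusted over the list alone are given.

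Named genes followed a rule of 3 parts. The first took, for each comparison, the 6 higher and 6 lower called genes with the largest fold change among those with a mean of at least 1 CPM, no overlap between the groups and a symbol that is not a predicted model. The second took up to 3 called members, with the smallest adjusted p, of each list that passed in its direction. The third was a panel given whatever its values: Gfap, Aif1, Lcn2, Hmox1, Trem2, Spp1, C3, Ccl2, Mki67, Fos, Slc17a7, Gad1, Mbp, Cldn5, Hba-a1, Ttr, Col1a1, S100a8 and Cd3e. Cd3e had too few counts to be tested (13 counts over the 14 samples). Counts over named genes include some whose own values are not reported here. Genes named outside the rule are marked as chosen after their values were seen.

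The procedure was tested on data simulated with this table's depth and dispersion. Of 100 genes truly changed 2-fold 69% were recovered, and of 100 changed 4-fold 96%, with 4 false calls among 169. A raised list ranked 1st of 37 and 0 others passed camera, which leaves correlated genes untested. The alternatives tried were DESeq2 size factors, no filter and a stricter filter on low counts (1 CPM in at least 4 samples), the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, robust estimation, a fit of only the 2 groups compared, the replicate number as a block, log2 FPKM with a pseudocount of 1 or 0.1, leaving out mitochondrial and haemoglobin genes, and leaving out each animal in turn. Samples with the same number in different groups were checked for a shared component before the block was used, and none was seen. The 2 contrasts with sham share the sham animals, so their overlap was set against simulated unchanged groups and against splits of the sham animals. Added after the data were seen were the striatal and choroid plexus scores as covariates, the assembled loci kept in, CVST 2 d animal 5 and CVST 7 d animal 2 left out together, list counts without single animals, and the exact permutation of the list scores. Figures were drawn with matplotlib 3.10.9.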

Results

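Gene expression in the cerebral cortex was measured in 14 mouse samples, called animals here: 4 sham animals, 5 animals at 2 d after CVST and 5 animals at 7 d after CVST. The total of gene counts averaged 18.5 M ± 1.40 (in M, for mega; SD, n = 4) in sham, 17.9 M ± 2.04 (SD, n = 5) at 2 d and 16.7 M ± 1.45 (SD, n = 5) at 7 d. Between 21739 and 23054 genes had a count in a sample. Mitochondrially encoded genes took 6.73% to 8.71% of the counts and the 10 most abundant genes 8.44% to 10.8%. Every library had at most 6 counts of Xist, the RNA of the inactive X chromosome, and 49.9 to 79.0 CPM (without TMM factors) of the Y-linked Ddx3y. Ttr, the transthyretin of the choroid plexus, ranged from 1.64 to 793 CPM and varied within each group. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.952 to 0.985 between samples of a group.

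The first principal component of log2 CPM held 33.1% of the variance and the second 14.9%. Sham animals lay at -48.2 to -27.3 on the first component. CVST 2 d animal 5 (-26.7) and CVST 7 d animal 2 (-26.9) lay on the same side, while the other CVST animals reached 49.1. The second component placed the 2 d animals at 0.0158 to 42.4 and the 7 d animals at -38.6 to -9.66.

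The first comparison asked which genes differed from sham in the damaged cortex at 2 d after CVST. The higher genes included 16 of 20 reactive astrocyte genes, 23 of 28 cell cycle genes, 10 of 21 chemokines and cytokines and 7 of 18 genes of activated endothelium and haemostasis. Of these 4 lists, reactive astrocytes also passed with an estimated correlation (adjusted p = 0.0279). Gfap (ENSMUSG00000020932), the intermediate filament of astrocytes, rose from 157 ± 22.8 CPM in sham to 1324 ± 493 CPM (SD, n = 4 and 5), a log2 fold change of 3.07 ± 0.41 (SE, adjusted p = 0.00371). Serpina3n (ENSMUSG00000021091), a secreted protease inhibitor, rose from 14.3 to 224 CPM (3.97 ± 0.47, adjusted p = 0.00367). Hmox1 (ENSMUSG00000005413), the enzyme that opens the haem ring, rose from 3.53 to 77.0 CPM (4.45 ± 0.85, adjusted p = 0.0154), a call that ended without sham 2, 3 or 4 (0.0586 to 0.0671). Nr4a1, an immediate early transcription factor, and Cort, the neuropeptide cortistatin, fell, by 0.95 ± 0.17 and 1.55 ± 0.27 on the log2 scale (SE, n = 4 and 5). Each of these genes was beyond the sham range in 5 of 5 CVST animals.

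Over all 16918 genes, 505 were higher and 164 lower at 2 d than in sham, of which 383 and 29 changed at least 2-fold. At an unadjusted p under 0.05, 2080 were higher and 1587 lower. Among the genes of largest fold change that the naming rule took, Tgm1, a transglutaminase, rose from 2 sham counts (pooled ratio 1509, counting interval 418 to 12468). Arg1, the arginase of alternatively activated macrophages, rose from 3 (219, interval 74.6 to 1063). Clec4d, a myeloid lectin receptor with 0 sham counts, was at least 47.1-fold higher. Msr1, a macrophage scavenger receptor, rose by 6.16 ± 1.15 (SE), Ptx3, a soluble pattern recognition protein, by 6.14 ± 0.89 and Ccl2, a monocyte chemokine, by 5.98 ± 1.29. Ccl2 had 5 sham counts, 4 of them in sham 2, and a sham mean of 0.0753 CPM, or 0.0196 without sham 2. Its 2 d mean was 4.86 CPM, or 2.87 without CVST 2 d 2, and its call ended without CVST 2 d 2 (adjusted p = 0.0521) or any 1 of the sham animals (0.0608 to 0.091). The 6 lower genes of the rule were H1f4 (-2.02), Cyp26b1, which degrades retinoic acid (-1.64), Cort, Fam180a (-1.43), Dnah7b (-1.35) and Prdm16os (-1.33).

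Of the 20 measured reactive astrocyte genes 16 rose (20 adjusted over the list alone), and their median log2 fold change was 2.71, with a camera adjusted p of 8.31e-34. Aspg rose by 2.51 ± 0.29 beside Gfap and Serpina3n. In CVST 2 d animal 5 the score of this list was 1.47, against 2.48 to 3.29 in the other 2 d animals. Of 28 cell cycle genes 23 rose (27 adjusted over the list alone; median 2.30, camera adjusted p = 3.45e-25), among them Tpx2 (1.91), Kif20a (3.77), Plk1 (2.27) and Mki67 (3.64 ± 0.77), whose call ended without any 1 of the sham animals (adjusted p = 0.054 to 0.0882). CVST 2 d animal 5 had a cell cycle score of -0.19, just below the sham range of -0.11 to 0.10, against 2.39 to 2.90 in the other 2 d animals. It did not pass with an estimated correlation (adjusted p = 0.118).

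The immune lists rose as groups. Of 21 chemokines and cytokines 10 rose (20 adjusted over the list alone), with a median of 4.08, or 3.52 with Ccl5 and Il1rn, which had 0 sham counts, at their bound. Cxcl1, a neutrophil chemokine, rose by 4.79 ± 0.74 and Ccl12 by 5.19 ± 0.87. Tnf was seen at 1 sham count (pooled ratio 41.3, interval 7.09 to 1665). The camera adjusted p of this list was 2.92e-20 (adjusted p = 0.0814 with an estimated correlation). Of 23 interferon response genes 11 rose (20 over the list alone; median 1.29, camera adjusted p = 8.52e-18, adjusted p = 0.118 with an estimated correlation), such as Irf9 (1.11), Usp18 (1.73) and Gbp2 (1.53). Pattern recognition and inflammasome genes had 9 of 21 higher (18 higher and 1 lower over the list alone; median 1.51), among them Cd14 (2.56 ± 0.38), Tlr13 (2.42) and Myd88 (1.13). Their camera adjusted p was 1.74e-14 (adjusted p = 0.118 with an estimated correlation). Complement had 7 of 17 higher (13 over the list alone; median 1.44; C4b 2.31, C5ar1 3.29, C3ar1 2.91, C3 3.12) at a camera adjusted p of 1.13e-11 (adjusted p = 0.118 with an estimated correlation).

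Monocytes and macrophages had 4 of 17 genes higher (13 over the list alone; median 2.59, camera adjusted p = 4.99e-10, adjusted p = 0.126 with an estimated correlation). Disease-associated microglia and lysosome genes had 3 of 20 higher (15 over the list alone; median 1.24; Cst7 4.45, Cd63 1.42, Cd9 1.52) at a camera adjusted p of 4.79e-09 (adjusted p = 0.301 with an estimated correlation). Antigen presentation had 4 of 18 higher (10 over the list alone; median 1.03; Cd86 1.52, Nlrc5 2.13, Tap1 1.36), at a camera adjusted p of 1.9e-07 (adjusted p = 0.315 with an estimated correlation). CVST 2 d animal 5 scored 0.06 for antigen presentation and 0.56 for disease-associated microglia, below the 0.58 to 1.73 and 1.32 to 2.15 of the other 2 d animals. Of 5 neutrophil genes 1 rose (3 over the list alone; Il1r2 2.13), with a median of 1.71 and a camera adjusted p of 0.000406 (adjusted p = 0.118 with an estimated correlation). For the panel genes Aif1 (1.00 ± 0.36, adjusted p = 0.125), Trem2 (0.93 ± 0.47, 0.262), Spp1 (4.57 ± 1.37, 0.0741; 2 d mean 224 CPM, or 135 without CVST 2 d 2), Lcn2 (3.94, 0.0707) and S100a8 (2.37 ± 0.75, 0.088) the difference did not pass.

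Activated endothelium and haemostasis had 7 of 18 genes higher (14 over the list alone), with a median of 1.62. Vwf, the platelet-binding factor of endothelium, rose by 1.50 ± 0.28 and Anxa2 by 2.23 ± 0.43, and the camera adjusted p was 1.15e-13 (adjusted p = 0.0814 with an estimated correlation). Haem and iron handling had 4 of 18 higher (5 over the list alone; median 0.44; ceruloplasmin Cp 0.92, Slc11a1 2.03) at a camera adjusted p of 0.000411 (adjusted p = 0.301 with an estimated correlation). Red cell and platelet genes had 0 of 5 called by edgeR (5 higher over the list alone and 5 at an unadjusted p under 0.05; median 3.37, camera adjusted p = 0.000197, adjusted p = 0.118 with an estimated correlation), Hba-a1 measuring 29.3 CPM at 2 d and 2.43 in sham (3.61 ± 0.99, adjusted p = 0.055). The 2 d mean of Hba-a1 was 13.3 CPM without CVST 2 d animal 2 (93.3 CPM), with the other 2 d animals at 6.38 to 32.6 CPM, and the sham mean was 1.32 CPM without sham 2 (5.75 CPM). Of 20 antioxidant and ferroptosis genes 6 rose (9 over the list alone; median 0.40, camera adjusted p = 1.07e-06), such as G6pdx (0.55) and Srxn1 (0.64). Fibroblast and matrix genes had 0 of 22 called by edgeR over all genes or the list alone (6 higher at an unadjusted p under 0.05), with a median of 0.69 and a camera adjusted p of 0.000468 (adjusted p = 0.559 with an estimated correlation). Col1a1 measured 1.21 ± 0.96 (adjusted p = 0.499).

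Stress and neuronal lists also passed camera. The p53 and apoptosis list had 2 of 20 genes higher (7 over the list alone; Cdkn1a, a cell cycle inhibitor, 1.50 ± 0.25; Tnfrsf12a 2.31), with a median of 0.22 and a camera adjusted p of 0.000133 (adjusted p = 0.118 with an estimated correlation). Hypoxia and glycolysis had 2 of 18 higher (4 higher and 2 lower over the list alone; median 0.18; Adm 1.79, Hk2 1.21; camera adjusted p = 0.0298, adjusted p = 0.163 with an estimated correlation). Heat shock and unfolded protein response had 1 of 15 higher (1 over the list alone; median 0.10; Atf3 3.27; camera adjusted p = 0.0309, adjusted p = 0.354 with an estimated correlation). Immediate early genes had 2 of 16 lower (3 over the list alone; median -0.14; Nr4a1 and Nr4a3, -1.29; camera adjusted p = 0.0117, adjusted p = 0.544 with an estimated correlation). Fos measured 0.41 ± 0.38 (adjusted p = 0.571). Synaptic transmission had 2 of 28 lower (2 over the list alone; median -0.23; the glutamate receptor subunit Gria3, -0.60, and the scaffold Dlg4, -0.27; camera adjusted p = 0.000133, adjusted p = 0.431 with an estimated correlation). With DESeq2 size factors Dlg4 was not called at 2 d (adjusted p = 0.0527). Inhibitory interneurons (0 of 16 called by edgeR, 5 lower at an unadjusted p under 0.05, median -0.29, camera adjusted p = 0.0107, adjusted p = 0.301 with an estimated correlation) passed as a list. So did mitochondrially encoded genes (0 of 13 called by edgeR, 2 lower at an unadjusted p under 0.05, median -0.18, camera adjusted p = 0.00745, adjusted p = 0.544 with an estimated correlation). The hypoxia list did not pass without sham 2 (adjusted p = 0.05004), CVST 2 d 1 (0.0513), 4 (0.0511) or 5 (0.0549). Heat shock did not pass without sham 1 (0.138) or CVST 2 d 1 (0.0567), nor did immediate early genes without CVST 2 d 1 (0.0522) or 5 (0.169) and mitochondrially encoded genes without sham 1 (0.0689) or CVST 2 d 4 (0.0961).

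The lists that did not pass at 2 d were homeostatic microglia (2 of 15 higher, median 0.21, camera adjusted p = 0.062), lymphocytes (0.05), homeostatic astrocytes (-0.21), oligodendrocytes and myelin (-0.17), oligodendrocyte precursors (-0.14), blood-brain barrier endothelium (0.07) and mural cells (0.16), each given with its median log2 fold change. Neither did excitatory cortical neurons (0.01, camera adjusted p = 0.968), neuronal ion channels (-0.08), cholesterol biosynthesis (-0.05), nuclear-encoded oxidative phosphorylation (-0.02), choroid plexus (-0.57), striatum (-0.97, camera adjusted p = 0.104), hippocampus (-0.51) and thalamus (-0.12). The neuronal markers Slc17a7 (0.18 ± 0.15) and Gad1 (0.14 ± 0.11), the myelin gene Mbp (-0.15 ± 0.28), the tight junction gene Cldn5 (0.35 ± 0.17) and Ttr (-0.57 ± 1.45) did not pass, at adjusted p of 0.51, 0.508, 0.795, 0.247 and 0.856. Scores of CVST 2 d animal 5 were -0.80 for myelin and 1.08 for striatum, against -0.04 to 0.20 and -1.66 to -0.54 in the other 2 d animals. Under other settings striatum passed without sham 1 (adjusted p = 0.00801), sham 3 (0.00357) or CVST 2 d 5 (0.0152, median -1.60), with the block (0.000368) and with no filter (0.0463). Homeostatic microglia passed without sham 2 (0.0395) or CVST 2 d 5 (0.00329), with the block (0.0464) and with no filter (0.0319). Ion channels passed without sham 3 (0.0334), sham 4 (0.00631) or CVST 2 d 3 (0.0168) and with no filter (0.0346), myelin (0.0334) and choroid plexus (0.0171) without sham 3, and hippocampus without sham 2 (0.0404).

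With an estimated correlation 2 of the 22 lists that passed camera at 2 d held, reactive astrocytes and antioxidant genes (adjusted p = 0.0279 each). With the exact permutation of the scores 15 lists passed (adjusted p = 0.0392, the smallest reached). The counts depended on single animals: without sham 1, 2, 3 or 4 they were 198, 78, 60 and 84 higher and 79, 19, 16 and 24 lower genes. Without CVST 2 d 1 to 5 they were 215, 186, 263, 229 and 1193 higher and 46, 61, 61, 86 and 774 lower genes. All 669 calls kept their direction where tested. Of 56 called genes named for this comparison, 10 were called in all 9 fits (Gfap, Serpina3n, Aspg, Ptx3, Cd14, Irf9, Cxcl1, Tgm1, Ccl12 and Cdkn1a). At most 1 fit called C3, C3ar1, Cd63, Cd9, Clec4d, Cyp26b1, Dlg4, Gria3, Hk2, Il1r2, Nlrc5, Slc11a1 and Tap1. The threshold was missed by 23, 39, 44 and 38 without sham 1, 2, 3 or 4 and 16, 18, 12, 15 and 0 without CVST 2 d 1 to 5. With voom and sample quality weights 3 of them missed it, Tgm1 (adjusted p = 0.0623), Cst7 (0.0862) and C3 (0.152).

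Counts of called list members moved with single animals and are given by edgeR in the order sham 1 to 4 left out, then CVST 2 d 1 to 5 left out. Reactive astrocytes (16) gave 12, 9, 9 and 10, then 11, 11, 14, 12 and 18. Cell cycle (23) gave 2, 0, 0 and 0, then 7, 6, 8, 7 and 27. Interferon response (11) gave 4, 3, 1 and 2, then 6, 4, 5, 9 and 18. Chemokines (10) gave 5, 5, 2 and 4, then 8, 5, 8, 8 and 15. Pattern recognition (9) gave 4, 1, 1 and 1, then 4, 3, 4, 4 and 12. Complement (7) gave 2, 0, 0 and 1, then 2, 1, 3, 2 and 12. Activated endothelium (7) gave 4, 0, 0 and 1, then 6, 5, 7, 5 and 10. Antioxidant genes (6) gave 5, 3, 0 and 1, then 6, 5, 6, 6 and 8. Monocytes and macrophages (4) gave 3, 1, 1 and 1, then 4, 3, 4, 5 and 7, antigen presentation (4) 1, 1, 0 and 0, then 1, 1, 1, 1 and 7, and haem and iron handling (4) 2, 0, 0 and 0, then 1, 1, 2, 1 and 4. Disease-associated microglia (3) gave 1 without CVST 2 d 3, 8 without CVST 2 d 5 and 0 without any other of these animals. Lists with 1 or 2 calls lay between 0 and 5. Red cell genes, with none, gave 5 higher and interneurons 4 lower without CVST 2 d 5.

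**Figure D1:**
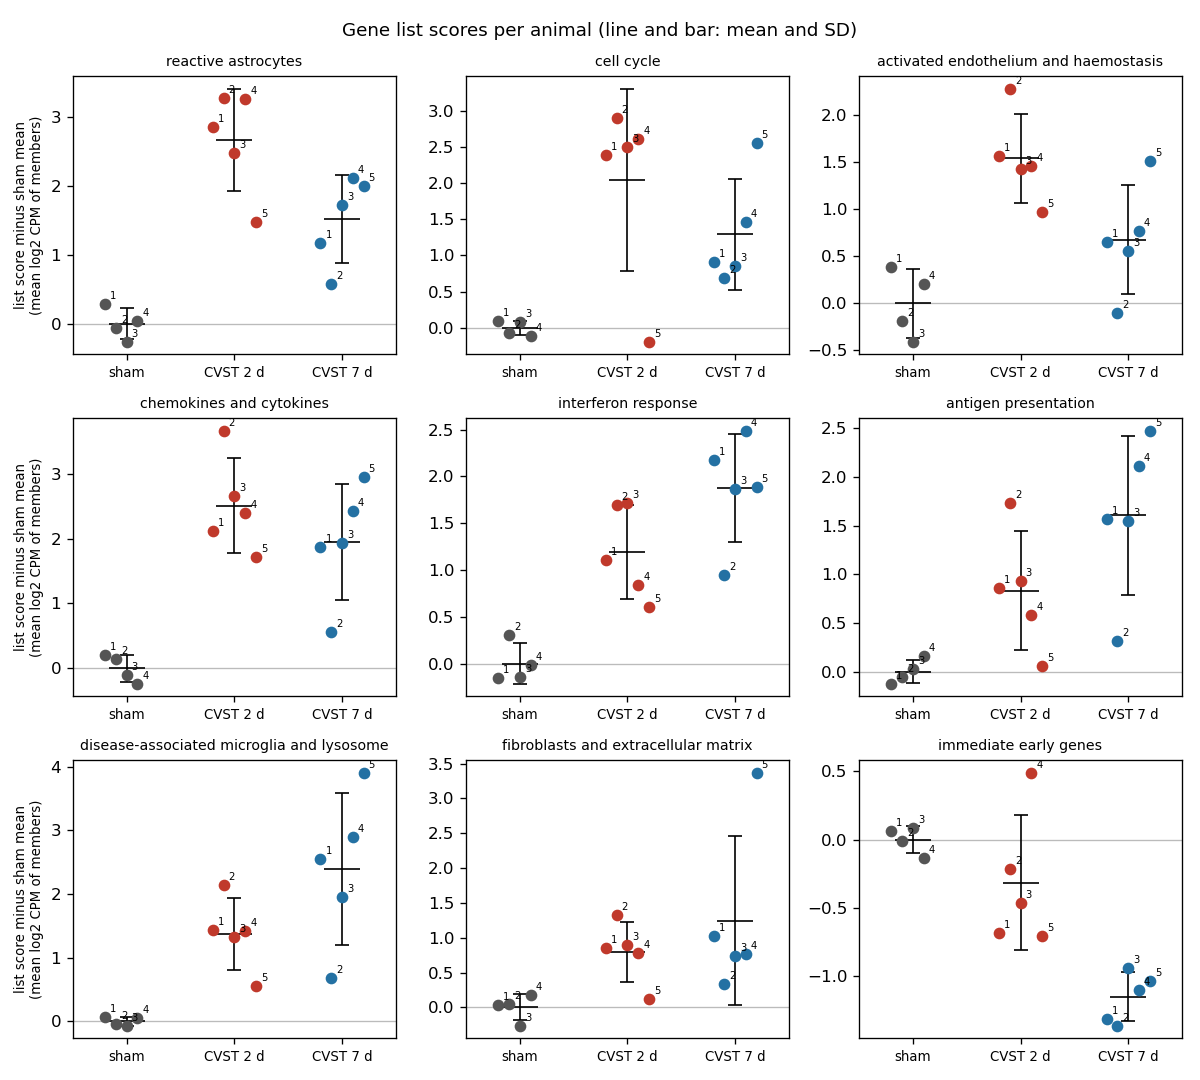
Score of 9 gene lists in each animal (points, numbered by animal), as mean log2 CPM minus the mean of the sham animals, for sham (n = 4), CVST 2 d (n = 5) and CVST 7 d (n = 5), with the group mean and SD as line and bar. CVST 2 d animal 5 lies at -0.19 for cell cycle genes while the other 2 d animals lie at 2.39 to 2.90, and CVST 7 d animal 5 lies at 3.37 for fibroblast and matrix genes while the other 7 d animals lie at 0.34 to 1.02.

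The second comparison asked which genes differed from sham at 7 d after CVST. The higher genes included 20 of 23 interferon response genes, 14 of 18 antigen presentation genes, 11 of 17 complement genes and 15 of 20 genes of disease-associated microglia, and the lower genes 10 of 16 immediate early genes. These lists passed camera but not with an estimated correlation (lowest adjusted p = 0.0632 with an estimated correlation). Clec7a (ENSMUSG00000079293), a receptor of disease-associated microglia, rose from 0.208 ± 0.0815 CPM in sham to 22.0 ± 18.0 CPM at 7 d (SD, n = 4 and 5), a log2 fold change of 6.68 ± 0.98 (SE, adjusted p = 0.00454). Gpnmb, a glycoprotein of lipid-laden phagocytes, rose from 2.65 to 217 CPM (6.36 ± 1.05, adjusted p = 0.00894). H2-K1, a class I antigen-presenting molecule, rose from 21 to 78.4 CPM (1.90 ± 0.30, adjusted p = 0.00747). Nr4a1 (ENSMUSG00000023034) fell from 87.2 to 31.6 CPM, by 1.46 ± 0.18 on the log2 scale (adjusted p = 0.00199). These 4 genes were beyond the sham range in 5 of 5 animals.

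At 7 d 611 genes were higher and 141 lower than in sham, 462 and 17 of them at least 2-fold, and 1981 and 1339 passed an unadjusted p under 0.05. Il1rn, the interleukin 1 receptor antagonist, had 0 sham counts and was at least 111-fold higher. Cd300lb was seen at 1 sham count (pooled ratio 182, interval 32.4 to 7238). The non-coding RNA H19 (6.79 ± 1.67), the lysosomal inhibitor Cst7 (6.53 ± 1.00) and the lysozyme Lyz2 (6.38 ± 1.18) completed the 6 higher genes of the rule with Clec7a. The 6 lower genes of the rule were Cort (-2.08 ± 0.28) and the immediate early genes Egr2 (-2.16 ± 0.44), Fos (-1.63 ± 0.39), Arc (-1.62 ± 0.32), Nr4a1 and Egr4 (-1.42 ± 0.21). H19 and Col1a1 got no adjusted p from DESeq2's Wald test, which sets aside genes with an outlying sample.

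Of 23 interferon response genes 20 rose (23 adjusted over the list alone), with a median of 2.10 and a camera adjusted p of 2.37e-41 (adjusted p = 0.0632 with an estimated correlation). Ifit3 rose by 2.17 ± 0.29 and Usp18 by 2.32 ± 0.34. Antigen presentation had 14 of 18 higher (16 over the list alone; median 1.97), among them Cd86 (2.20) and H2-D1 (2.03), at a camera adjusted p of 1.37e-21 (adjusted p = 0.104 with an estimated correlation). Complement had 11 of 17 higher (15 higher and 1 lower over the list alone; median 2.19), with C4b at 2.87, C3 at 4.82 and the microglial component C1qa at 2.35. Its camera adjusted p was 4.54e-19 (adjusted p = 0.101 with an estimated correlation). Pattern recognition had 14 of 21 higher (19 over the list alone; median 1.53; Tlr13 2.60, Tlr7 1.86, Tlr2 3.31). Chemokines and cytokines had 11 of 21 higher (16 over the list alone; median 2.68; Cxcl10 3.91, Cxcl16 2.45). The camera adjusted p of the 2 lists were 4.53e-17 and 4.19e-15 (adjusted p = 0.104 each with an estimated correlation). Tnf again had 1 sham count (pooled ratio 40.7, interval 6.95 to 1643), and Ccl2 did not pass (4.21 ± 1.33, adjusted p = 0.0929). The 7 d mean of Ccl2 was 1.40 CPM, or 0.582 without CVST 7 d 5 (4.67 CPM), and that of C3 was 10.3 CPM, or 6.73 without CVST 7 d 4.

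Disease-associated microglia and lysosome genes had 15 of 20 higher at 7 d (20 over the list alone; median 2.05, camera adjusted p = 7.29e-24, adjusted p = 0.104 with an estimated correlation). The panel genes Trem2, a lipid receptor of microglia (2.23 ± 0.48), Spp1, osteopontin (6.83 ± 1.51), and Aif1 (1.42 ± 0.36) passed as well. Spp1 measured 4108 CPM in CVST 7 d animal 5 against 9.31 to 746 CPM in the others, and its 7 d mean was 310.4 CPM without that animal. In CVST 7 d animal 2 Spp1 (9.31 CPM) and Aif1 (4.31 CPM) lay within the sham ranges of 6.65 to 14.2 and 3.27 to 4.71 CPM. All 3 calls ended without any 1 of the 4 sham animals (adjusted p = 0.0539 to 0.121). Those of Trem2 (0.0537) and Aif1 (0.106) ended without CVST 7 d 4, and that of Aif1 also without CVST 7 d 1 (0.0548) or 5 (0.0915) and with voom (0.0562). CVST 7 d animal 2 scored 0.68 for this list and CVST 7 d animal 5 scored 3.91, with the other 7 d animals at 1.95 to 2.89. For antigen presentation animal 2 scored 0.32, against 1.55 to 2.48 in the others. Homeostatic microglia had 3 of 15 higher (11 over the list alone; median 0.69; Csf1r 1.22, Cx3cr1 1.12; camera adjusted p = 1.29e-09, adjusted p = 0.177 with an estimated correlation). Monocytes and macrophages had 8 of 17 higher (14 over the list alone; median 2.91; Cd14 1.84, Ms4a6c 3.72; camera adjusted p = 1.11e-09, adjusted p = 0.161 with an estimated correlation), with animal 2 at 0.00 and the other 7 d animals at 1.71 to 3.65.

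Immediate early genes, which neurons induce with activity, had 10 of 16 lower (15 over the list alone), with a median of -1.06 and a camera adjusted p of 6.36e-22 (adjusted p = 0.0632 with an estimated correlation). All 5 animals at 7 d scored -1.36 to -0.94, below the sham range of -0.14 to 0.08. Excitatory cortical neuron genes had a median of 0.01 with 0 of 17 called by edgeR and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.999). Inhibitory interneurons had 1 of 16 lower (3 over the list alone; Dlx1 -0.36; median -0.28, camera adjusted p = 0.000285, adjusted p = 0.161 with an estimated correlation). Synaptic transmission had 2 of 28 lower (3 over the list alone; Dlg4 -0.27, Shank3 -0.27; median -0.11, camera adjusted p = 0.00058, adjusted p = 0.415 with an estimated correlation). Shank3 was not called with DESeq2 size factors (adjusted p = 0.0549). Mitochondrially encoded genes had 2 of 13 lower (7 over the list alone; mt-Co2 -1.04, mt-Atp6 -0.67; median -0.23, camera adjusted p = 1.33e-06, adjusted p = 0.25 with an estimated correlation). Nuclear-encoded oxidative phosphorylation (0 of 26 called by edgeR, 5 lower at an unadjusted p under 0.05, median -0.15, camera adjusted p = 0.000115, adjusted p = 0.433 with an estimated correlation) was lower as a list. So was cholesterol biosynthesis (0 of 24 called by edgeR, 7 lower at an unadjusted p under 0.05, median -0.24, camera adjusted p = 0.00014, adjusted p = 0.415 with an estimated correlation).

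Reactive astrocytes had 7 of 20 genes higher at 7 d (10 over the list alone; median 1.74, camera adjusted p = 5.27e-14, adjusted p = 0.104 with an estimated correlation), with Gfap at 2.76 ± 0.40, Serpina3n at 2.97 ± 0.45 and Aspg at 2.10 ± 0.29. Homeostatic astrocytes had 1 of 16 higher, the water channel Aqp4 (0.90 ± 0.22; 2 over the list alone; median 0.22, camera adjusted p = 0.00814, adjusted p = 0.397 with an estimated correlation). Cell cycle genes had 1 of 28 higher (19 over the list alone; Cdk1 3.94; median 1.47, camera adjusted p = 1.72e-11, adjusted p = 0.32 with an estimated correlation). Mki67 measured 2.75 ± 0.75 (adjusted p = 0.0536), with a 7 d mean of 9.65 CPM, or 5.15 without CVST 7 d animal 5 (27.6 CPM). Fibroblasts and extracellular matrix had 3 of 22 higher (18 over the list alone), the collagens Col1a1 (4.47 ± 1.07), Col3a1 (4.73) and Col1a2 (3.54 ± 0.93). Its median was 1.54 (camera adjusted p = 2.66e-08, adjusted p = 0.327 with an estimated correlation). It was 0.54 without CVST 7 d animal 5, which had 879 CPM of Col1a1 against 20.02 to 71.4 CPM in the other 7 d animals. The calls of Col1a1 (adjusted p = 0.0764 to 0.106) and Hmox1 (0.0695 to 0.106) ended without any 1 of the sham animals, and that of Hmox1 also without CVST 7 d 4 (0.0649) or 5 (0.0644). Haem and iron handling had 4 of 18 higher (5 over the list alone; Slc11a1 2.94, Hmox1 3.46, the iron exporter Slc40a1 1.09; median 0.45, camera adjusted p = 5.59e-05, adjusted p = 0.25 with an estimated correlation). Antioxidant and ferroptosis genes had 2 of 20 higher (4 over the list alone; Sat1 1.02; median 0.18, camera adjusted p = 0.0175, adjusted p = 0.161 with an estimated correlation). Activated endothelium and haemostasis had 1 of 18 higher (4 over the list alone; Icam1 1.62; median 0.40, camera adjusted p = 0.000756, adjusted p = 0.337 with an estimated correlation).

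Heat shock and unfolded protein response had 1 gene higher and 2 lower of 15 (Dnajb1 -0.40, Xbp1 -0.40), with a median of -0.20 but a mean of 0.05. Camera called this list lower (adjusted p = 0.00974, adjusted p = 0.279 with an estimated correlation). Choroid plexus had 0 of 13 called by edgeR (6 lower at an unadjusted p under 0.05), a median of -1.86 and a camera adjusted p of 0.00814 (adjusted p = 0.486 with an estimated correlation), which was 0.23 without sham 4. Ttr measured -3.35 ± 1.56 (adjusted p = 0.251; sham mean 273 CPM, 100 without sham 4; 7 d mean 26.7, 7.22 without CVST 7 d 4). The homeostatic astrocyte list did not pass without CVST 7 d animal 4 (adjusted p = 0.0679). The lists that did not pass at 7 d, with their median log2 fold change, were neutrophils (0.85; 1 of 5 called), lymphocytes (-0.14), oligodendrocytes and myelin (0.19), oligodendrocyte precursors (0.11), blood-brain barrier endothelium (0.16) and mural cells (-0.02). Others were hypoxia and glycolysis (-0.11; 1 higher and 2 lower of 18), p53 and apoptosis (0.08; 2 of 20 higher), neuronal ion channels (-0.10), red cells and platelets (0.01), striatum (-0.79, camera adjusted p = 0.0528), hippocampus (-0.05) and thalamus (0.21). Of the panel, Lcn2 (1.79 ± 1.12), Slc17a7 (0.01 ± 0.15), Gad1 (-0.18 ± 0.11), Mbp (0.16 ± 0.28), Cldn5 (-0.02 ± 0.17), Hba-a1 (0.01 ± 0.98) and S100a8 (0.13 ± 0.82) did not pass, at adjusted p of 0.406, 0.991, 0.419, 0.8, 0.974, 0.998 and 0.949. The 7 d mean of Lcn2 was 4.57 CPM, and 1.32 without CVST 7 d animal 3 (17.6 CPM), beside 1.33 CPM in sham (0.797 without sham 1). CVST 7 d animal 5 scored 1.34 for striatum and the other 7 d animals -1.41 to -1.06. Striatum passed without that animal (adjusted p = 4.97e-05, median -1.64), sham 1 (0.00265) or sham 3 (0.000847), with size factors (0.0459), with the block (2.08e-05) and with no filter (0.0169). Myelin passed without sham 1 (2.52e-05, median 0.53) or CVST 7 d 3 (0.0168) and with the block (0.026). Neutrophils passed without sham 1 (0.0368), 3 (0.0191) or 4 (0.0121), p53 without sham 1 (0.0246) and with the block (0.0424), ion channels without sham 3 (0.0231), sham 4 (0.00252) or CVST 7 d 1 (0.00123) and with no filter (0.0147), and lymphocytes with no filter (0.00702).

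The 23 lists that passed camera at 7 d did not hold with an estimated correlation (lowest adjusted p = 0.0632). With the exact permutation of the scores 14 passed (adjusted p = 0.042, the smallest reached). Without sham 1, 2, 3 or 4 the counts were 266, 156, 101 and 126 higher and 65, 25, 18 and 22 lower genes. Without CVST 7 d 1 to 5 they were 536, 892, 581, 244 and 335 higher and 100, 143, 102, 35 and 69 lower genes. All 752 calls kept their direction where tested. Of 56 called genes named for this comparison 22 were called in all 9 fits, Clec7a, Cst7, Gpnmb, Ifit3, Usp18, Cd86, H2-K1, C4b, C3, C1qa, Nr4a1, Egr4, Cort, Gfap and Serpina3n among them. Fos, Cx3cr1, Shank3, Xbp1 and mt-Atp6 were called in 1 of 9 fits, and Dlx1 was lost in each (adjusted p up to 0.135). With the block Fos was not called (0.0988). The threshold was missed by 23, 29, 34 and 30 without sham 1, 2, 3 or 4 and 6, 4, 9, 18 and 14 without CVST 7 d 1 to 5. With voom and sample quality weights 15 of them missed it, among them Clec7a (adjusted p = 0.0735), Gpnmb (0.0576), Hmox1 (0.135), Spp1 (0.14), C3 (0.0846), Cdk1 (0.244), H19 (0.159) and the collagens Col1a1 (0.0616), Col3a1 (0.0932) and Col1a2 (0.0671).

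In the same order, sham 1 to 4 and then CVST 7 d 1 to 5 left out, the called members by edgeR at 7 d were as follows. Interferon response (20) gave 16, 16, 13 and 15, then 18, 22, 19, 16 and 19. Disease-associated microglia (15) gave 8, 4, 4 and 4, then 14, 18, 16, 10 and 13. Antigen presentation (14) gave 8, 5, 6 and 5, then 11, 15, 12, 8 and 9. Pattern recognition (14) gave 5, 2, 0 and 2, then 13, 16, 10, 4 and 6. Chemokines (11) gave 3, 2, 1 and 1, then 10, 15, 11, 2 and 3. Complement (11) gave 10, 8, 4 and 7, then 11, 14, 11, 9 and 9. Immediate early genes (10 lower) gave 4, 3, 2 and 4, then 5, 10, 9, 5 and 5. Monocytes and macrophages (8) gave 3, 1, 0 and 0, then 8, 9, 8, 5 and 5, and reactive astrocytes (7) 7, 5, 4 and 4, then 7, 8, 7, 5 and 6. Haem and iron handling (4) gave 1 without each sham animal, then 4, 4, 2, 1 and 1. Homeostatic microglia (3) gave 1, 0, 0 and 0, then 2, 8, 2, 2 and 2, and matrix genes (3) 0 without each sham animal, then 3, 9, 3, 2 and 3. Lists with 1 or 2 calls in a direction lay between 0 and 4.

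**Figure D2:**
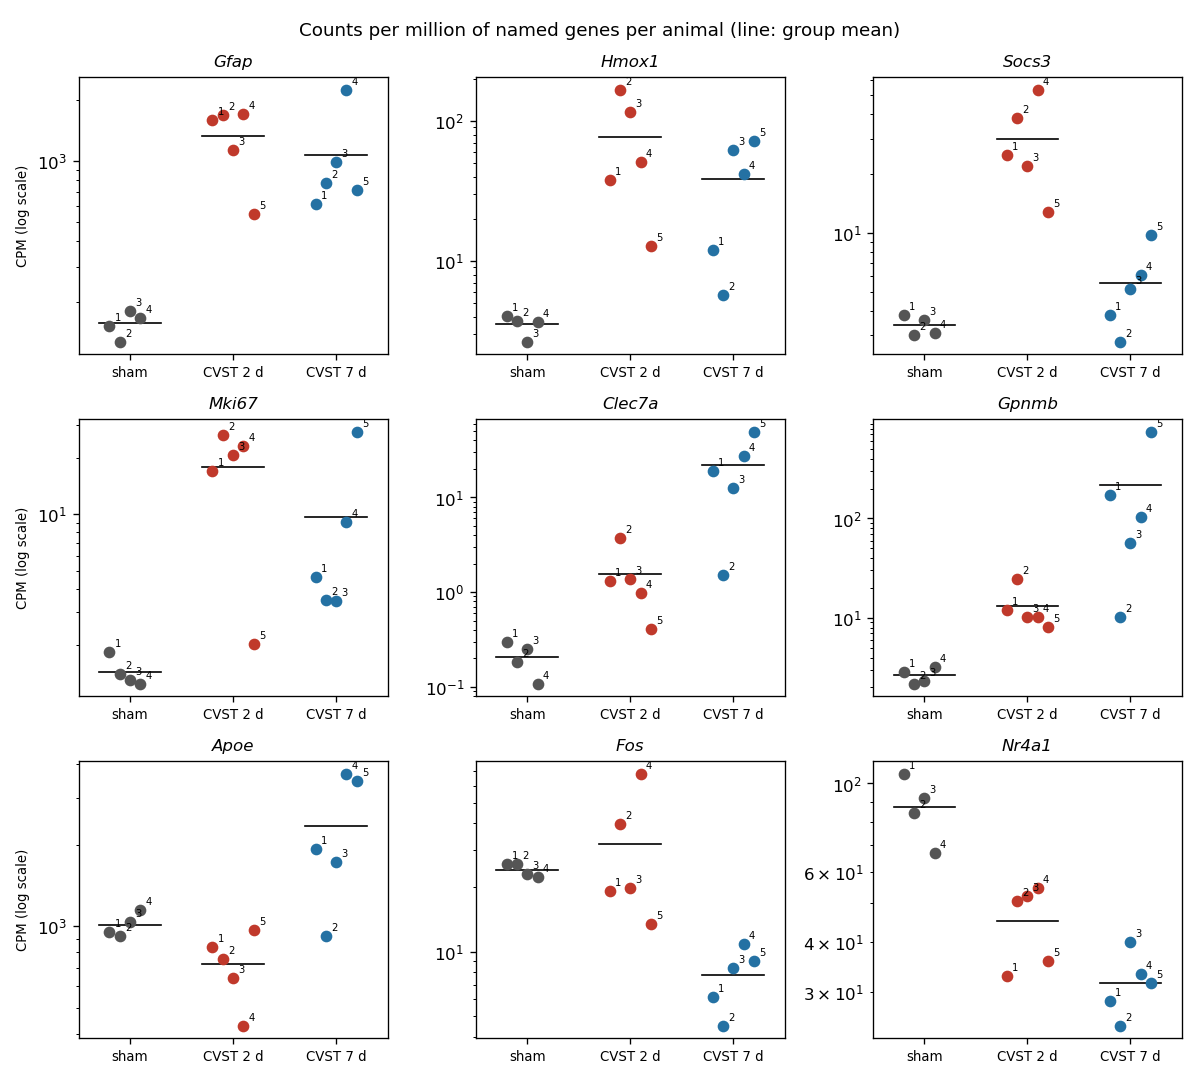
CPM on a log axis of 9 genes in each animal (points, numbered by animal) of sham (n = 4), CVST 2 d (n = 5) and CVST 7 d (n = 5), with the group mean as line. Gfap and Hmox1 lie above the sham range in all CVST animals, Clec7a and Gpnmb reach 22.0 and 217 CPM on average at 7 d, and Nr4a1 falls from a mean of 87.2 CPM in sham to 31.6 CPM at 7 d.

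The third comparison set 7 d directly against 2 d and so tested whether the effects at the 2 times differ. The genes lower at 7 d than at 2 d included 5 of 20 reactive astrocyte genes, 4 of 18 genes of activated endothelium and haemostasis and 6 of 16 immediate early genes, and the higher genes 5 of 20 genes of disease-associated microglia and 4 of 16 of homeostatic astrocytes. These lists passed camera, but no list passed with an estimated correlation (lowest adjusted p = 0.0981 with an estimated correlation) or with the exact permutation (lowest adjusted p = 0.0979). Lag3, an inhibitory receptor, rose from 3.67 ± 1.05 CPM at 2 d to 20.01 ± 7.54 CPM at 7 d (SD, n = 5 and 5; log2 fold change 2.45 ± 0.28, adjusted p = 0.00276). Clec7a rose from 1.57 to 22.0 CPM (3.78 ± 0.70, adjusted p = 0.0156) and Apoe, the lipid carrier of astrocytes and microglia, from 728 to 2350 CPM (1.69 ± 0.31, adjusted p = 0.0156). Socs3, a feedback inhibitor of cytokine signals, fell from 30.1 to 5.52 CPM (-2.44 ± 0.37, adjusted p = 0.00698), and Selp, the platelet and endothelial adhesion molecule P-selectin, from 2.60 to 0.149 CPM (-4.04 ± 0.79, adjusted p = 0.0177). Lag3, Socs3 and Selp lay beyond the 2 d range in 5 of 5 animals at 7 d, and Clec7a and Apoe in 4 of 5.

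Between 2 d and 7 d 261 genes were higher and 212 lower, 88 and 78 of them at least 2-fold, and 1745 and 1795 passed an unadjusted p under 0.05. Under the naming rule (no overlap between the groups, a mean of at least 1 CPM) the other genes of largest increase were H1f4 (2.48 ± 0.38), Fam180a (2.08 ± 0.32), the small proteoglycan Fmod (1.96 ± 0.44), Kcne1l (1.91 ± 0.35) and Ddx60, an RNA helicase induced by interferon (1.84 ± 0.33). Those of largest decrease were the cytokine Il11 (-4.81 ± 0.75), Fndc9 (-2.74 ± 0.63), the small heat shock protein Hspb1 (-2.47 ± 0.40) and the kinin receptor Bdkrb2 (-2.13 ± 0.45).

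Reactive astrocytes had 5 of 20 genes lower at 7 d than at 2 d (9 adjusted over the list alone), with a median of -1.06 and a camera adjusted p of 5.84e-09 (adjusted p = 0.287 with an estimated correlation). Tm4sf1 fell by 1.87 and S100a10 by 1.13, while Gfap measured -0.32 ± 0.35 (adjusted p = 0.643). Homeostatic astrocytes had 4 of 16 higher (6 over the list alone; median 0.28, camera adjusted p = 0.000203, adjusted p = 0.425 with an estimated correlation), the gap junction gene Gja1 at 0.93 ± 0.17, the glutamate transporter Slc1a2 at 0.74 ± 0.15 and Ndrg2 at 0.60 ± 0.14. Activated endothelium and haemostasis had 4 of 18 lower (7 over the list alone; median -0.59; Lrg1 -1.91), at a camera adjusted p of 4.45e-06 (adjusted p = 0.321 with an estimated correlation). Hypoxia and glycolysis had 2 of 18 lower (8 over the list alone; median -0.27; Ldha -0.66, Adm -1.49; camera adjusted p = 6.41e-05, adjusted p = 0.0981 with an estimated correlation). Heat shock and unfolded protein response had 2 of 15 lower (8 over the list alone; median -0.39; Xbp1 -0.50, Atf4 -0.51; camera adjusted p = 4e-07, adjusted p = 0.0981 with an estimated correlation). Antioxidant genes had 4 of 20 lower (median -0.12; Ptgs2 -1.29, Gsr -0.46, Srxn1 -0.58; camera adjusted p = 0.00621, adjusted p = 0.152 with an estimated correlation). The p53 list had 3 lower and 1 higher of 20 (Cdkn1a -1.67 ± 0.23, Tnfrsf12a -2.27, Aen -0.41; median -0.10, camera adjusted p = 0.0222, adjusted p = 0.45 with an estimated correlation). It did not pass without CVST 2 d 2 (adjusted p = 0.0655) or CVST 7 d 3 (0.0608).

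Immediate early genes had 6 of 16 lower (14 over the list alone; median -0.85; Fos -2.04 ± 0.38, Arc -1.48, Junb -1.03; camera adjusted p = 1.15e-11, adjusted p = 0.152 with an estimated correlation). Fos was not called with the block (adjusted p = 0.0532) or with only the 2 groups fitted (0.0563). Cell cycle genes had 0 of 28 called by edgeR over all genes or the list alone (5 lower at an unadjusted p under 0.05), with a median of -0.84 and a camera adjusted p of 1.52e-06 (adjusted p = 0.522 with an estimated correlation). Red cell and platelet genes had 1 of 5 lower, Hba-a1 (-3.60 ± 0.91), and 5 over the list alone, Hba-a1 being called in 1 of 10 fits with 1 animal left out, and neither with the block (adjusted p = 0.166) nor with only the 2 groups fitted (0.0963). Its 2 d mean was 13.3 CPM without CVST 2 d animal 2, and its 7 d mean of 2.46 CPM was 1.45 without CVST 7 d 1. The list passed (median -3.36, camera adjusted p = 4.42e-05, adjusted p = 0.152 with an estimated correlation). Disease-associated microglia had 5 of 20 higher (11 over the list alone; median 1.17; Gpnmb 4.05), at a camera adjusted p of 4.08e-07 (adjusted p = 0.45 with an estimated correlation). Homeostatic microglia had 1 of 15 higher, the purinergic receptor P2ry12 (0.99 ± 0.23; 5 over the list alone; median 0.51, camera adjusted p = 4.42e-05, adjusted p = 0.45 with an estimated correlation). Interferon response had 1 of 23 higher, Rsad2 (1.64 ± 0.40; 11 over the list alone; median 0.73, camera adjusted p = 4e-07, adjusted p = 0.45 with an estimated correlation). Antigen presentation had 0 of 18 called by edgeR over all genes, 6 higher over the list alone and 9 at an unadjusted p under 0.05 (median 0.78, camera adjusted p = 5.91e-06, adjusted p = 0.462 with an estimated correlation). The lists for complement (1 of 17 higher, C2 1.50; median 0.57, camera adjusted p = 0.0284), oligodendrocytes and myelin (1 of 16 higher; median 0.18, 0.0137) and matrix (0 of 22 called by edgeR over all genes, 5 over the list alone and 7 higher at an unadjusted p under 0.05; median 0.66, 0.0333) passed, with adjusted p = 0.742, 0.756 and 0.785 with an estimated correlation. Complement did not pass without CVST 2 d 4 (adjusted p = 0.0643), CVST 2 d 5 (0.215), CVST 7 d 4 (0.152) or CVST 7 d 5 (0.329). Neither did oligodendrocytes without CVST 2 d 5 (0.386), CVST 7 d 4 (0.162) or CVST 7 d 5 (0.0602), nor matrix without CVST 2 d 5 (0.315) or CVST 7 d 5 (0.593, median 0.00). With the block complement (0.0638) and matrix (0.0653) did not pass.

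Cholesterol biosynthesis (0 of 24 called by edgeR over all genes, 2 lower over the list alone and 10 at an unadjusted p under 0.05; median -0.25, camera adjusted p = 0.000128, adjusted p = 0.522 with an estimated correlation) and nuclear-encoded oxidative phosphorylation (0 of 26 called by edgeR, 8 lower at an unadjusted p under 0.05; median -0.13, camera adjusted p = 0.000207, adjusted p = 0.597 with an estimated correlation) were lower as lists. The lists that did not pass between the times, with their medians, were monocytes and macrophages (0.13), neutrophils (-1.22), lymphocytes (-0.03), oligodendrocyte precursors (0.03), blood-brain barrier endothelium (-0.03), mural cells (-0.02), chemokines and cytokines (0.06, with 3 of 21 lower), pattern recognition (0.21), haem and iron handling (-0.02), excitatory cortical neurons (-0.01), inhibitory interneurons (-0.05), synaptic transmission (0.03), neuronal ion channels (-0.03), mitochondrially encoded genes (-0.08), choroid plexus (-0.84), striatum (0.04), hippocampus (0.49) and thalamus (0.46). Under other settings camera called the chemokine list lower, without CVST 2 d 5 (adjusted p = 0.0157, median -0.01), CVST 7 d 4 (0.019, 0.06) or CVST 7 d 5 (0.00444, -0.68), with the block (0.0375, -0.13) and with no filter (0.0352, 0.01). Neutrophils passed without CVST 2 d 1 (0.00824), CVST 7 d 4 (0.0277) or 5 (0.045) and with no filter (0.000792). Thalamus passed without CVST 2 d 1 (0.0367) or 4 (0.0491), CVST 7 d 1 (0.0201) or 2 (0.0163) and with no filter (0.0257), and choroid plexus without CVST 2 d 2 (0.0137) or 3 (0.0118), CVST 7 d 4 (0.0145) and with no filter (0.0396). Mitochondrially encoded genes passed without CVST 2 d 4 (0.000141) or CVST 7 d 1 (0.0355) and with no filter (0.0115), and precursors without CVST 7 d 1 (0.0234), 2 (0.0495) or 3 (0.0475). Pattern recognition passed without CVST 7 d 2 (0.044), synaptic transmission without CVST 7 d 5 (0.0343) and lymphocytes with no filter (0.0316). Panel genes without a call between the times included Hmox1 (-0.99 ± 0.64, adjusted p = 0.398), Spp1 (2.25 ± 1.09, 0.256), Trem2 (1.30 ± 0.42, 0.105), C3 (1.69 ± 0.60, 0.127), Mki67 (-0.89 ± 0.61, 0.419) and Col1a1 (3.26 ± 0.91, 0.0684).

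The 19 lists that passed camera between the times did not hold with an estimated correlation (lowest adjusted p = 0.0981) or with the exact permutation of the scores (lowest adjusted p = 0.0979, with 10 lists at an unadjusted p under 0.05), and 5 passed with fry. Without CVST 2 d 1 to 5 the counts were 98, 243, 128, 136 and 604 higher and 75, 156, 115, 92 and 705 lower genes. Without CVST 7 d 1 to 5 they were 147, 285, 150, 109 and 189 higher and 100, 124, 91, 88 and 192 lower genes. All 473 calls kept their direction where tested. Of 40 called genes named here 20 were called in every fit that tested them. Lag3, Clec7a, Apoe, Socs3, Selp, Hspb1, Cdkn1a, Fos, Gja1 and Ldha were among them, called in all 10 fits. Il11 was tested in only 6 fits and called in these 6. The threshold was missed by 15, 5, 11, 12 and 0 without CVST 2 d 1 to 5 and 12, 6, 12, 15 and 7 without CVST 7 d 1 to 5. With voom and sample quality weights 5 missed it, among them Clec7a (adjusted p = 0.0906), Gpnmb (0.0889), Fndc9 (0.0669) and Hba-a1 (0.0574).

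Called list members between the times also moved, and are given by edgeR with CVST 2 d 1 to 5 and then CVST 7 d 1 to 5 left out. Immediate early genes (6 lower) gave 5, 5, 3, 3 and 9, then 1, 4, 4, 2 and 4. Reactive astrocytes (5 lower) gave 5, 5, 5, 4 and 8, then 4, 5, 5, 4 and 5. Disease-associated microglia (5 higher) gave 2, 4, 2, 2 and 5, then 4, 8, 5, 3 and 4. Homeostatic astrocytes (4 higher) gave 1, 3, 2, 3 and 5, then 2, 2, 2, 2 and 4. Activated endothelium (4 lower) gave 1, 1, 2, 1 and 5, then 1, 1, 1, 2 and 5. Antioxidant genes gave 4 lower in each of the 10 fits, chemokines (3 lower) 1, 2, 2, 1 and 3, then 2 in each, and the p53 list (3 lower) 2, 3, 3, 3 and 4, then 3, 3, 2, 3 and 3. Lists with 1 or 2 calls in a direction lay between 0 and 5. With none, cell cycle genes gave 7 lower without CVST 2 d 5 and antigen presentation 5 higher without CVST 7 d 2.

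Set against each other, the 2 contrasts with sham shared 167 higher genes, where 18.2 would be shared if the calls were independent, and 34 lower genes, where 1.37 would be. By edgeR 0 genes were called in opposite directions, and at an unadjusted p under 0.05 in both contrasts 33 were opposite and 1393 alike in direction. The simulated unchanged groups described next gave a mean of 0.6 opposite and 195.4 alike. Because both contrasts use the same sham animals, they are correlated even without any effect. Across the 16918 genes, which are not independent replicates, r of the log2 fold changes was 0.76. In 20 simulations of unchanged groups its mean was 0.557 and its highest 0.586. These held at most 1 call per direction, too few to test sharing. The share of genes with the same sign was 67.9%, against a mean of 68.6% in these simulations and 55.8% to 63.0% with the sham animals split. With the sham animals split 2 and 2 between the contrasts, r was 0.496 to 0.629 over 6 assignments, with 0 shared genes but at most 16 higher genes called in either contrast. The covariance of the fold changes was 0.313 as observed, 0.0449 in the simulations and 0.251 to 0.294 with the sham animals split.

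By time, 85 genes were early higher and 47 early lower, 165 sustained higher and 33 sustained lower, and 69 late higher and 16 late lower. Early higher genes included Il11, Selp, Cxcl1, Tgm1, Ptx3, Hspb1, Socs3, Tnfrsf12a and Cdkn1a, and 5 reactive astrocyte genes, 3 antioxidant genes, 3 chemokines or cytokines and 3 genes of activated endothelium and haemostasis. Sustained higher genes included Serpina3n, C3, Ccl12, Hmox1, Ifit3, Cst7 and Slc11a1, and 11 interferon response genes, 7 pattern recognition genes, 6 complement genes and 6 reactive astrocyte genes. Late higher genes included Clec7a, Gpnmb, Lag3, Ddx60 and Rsad2, with 4 genes of disease-associated microglia. Cort, Nr4a1 and Nr4a3 were sustained lower, Fos, Arc, Junb and Xbp1 late lower, and H1f4, Fam180a, Dnah7b and Prdm16os early lower. Sustained higher genes are those without a call between the times, which does not show that their levels were equal. Without sham 1 to 4 the early higher genes numbered 52, 27, 20 and 31, the sustained 47, 23, 12 and 17 and the late 35, 21, 14 and 21. Without CVST 2 d 1 to 5 they numbered 38, 46, 55, 36 and 363 (early), 84, 64, 82, 90 and 344 (sustained) and 29, 81, 35, 38 and 89 (late). Without CVST 7 d 1 to 5 they numbered 45, 55, 43, 52 and 101, 131, 283, 138, 100 and 158, and 42, 154, 45, 22 and 37.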

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

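The tests of neuron share, striatal share, both wrong labels, library depth and vessel wall below were chosen only after the result was seen. Those of the clock genes, the leptomeninges and the other splits of the animals were set before their results were seen.

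Immediate early genes were lower at 7 d than in sham, with a median log2 fold change of -1.06 and all 5 animals below the sham range. Fewer neurons would lower the excitatory cortical neuron list too, and its median was 0.00526 (17 genes), which argues against that as the source. With the striatal score of each animal as a covariate the immediate early median was -1.07 and 9 of the 10 called genes were called (Nr4a3 -1.07 before and -1.06 after, adjusted p = 0.0378 and 0.0504), which argues against the share of striatum as the whole source. Collection at another time of day cannot be told apart from the effect of CVST, because the output arm of the clock (0.13) and the positive arm (-0.14) lay 0.275 apart, between the 2 bounds set beforehand, and the labels give no hour of collection. A biological effect of the 7 d group stays open as a hypothesis, and no biological explanation beyond the groups was tested.

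CVST 2 d animal 5 lacked the rise in cell cycle genes of the other 2 d animals (score -0.19, gap 0.836 of the group's range; Mki67 log2 CPM of 1.10 against a median of 4.39, gap 0.824), and its myelin score was the lowest of the group (-0.80, gap 0.764). A sham animal under the wrong label would score within sham for reactive astrocytes, and this library lay 5.18 sham SD above the highest sham animal, which argues against that. Low depth is argued against by its 17.4 M counts, within the range of the other 2 d libraries. On the genes called between the times its position was 0.668 (2 d mean 0, 7 d mean 1), 0.0936 above the lowest 7 d animal. Sham animals lay at 0.765 to 0.875, so position cannot single out a 7 d library. This library's cell cycle score lay below the 7 d lowest of 0.68 and its immediate early score of -0.71 above the 7 d highest of -0.94. Both argue against a mislabelled 7 d library. No biological explanation was tested, as the design names no difference between animals of a group.

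The matrix genes of CVST 7 d animal 5 (score 3.37, gap 0.776 of the group's range) exceeded the mean of the other 7 d animals by 2.66, and its striatal score was the highest of the group (1.34, gap 0.873). More meninges in its tissue would raise the resting leptomeninges list, which exceeded the others by 0.39 (SD of the others 0.31), a share of 0.148 of the matrix excess, and that argues against meninges as the whole source. More vessel wall cannot be told apart, since the mural cell list exceeded the others by 0.68 (SD 0.17), a share of 0.256 that fell between the bounds. No biological explanation was tested for a single animal.

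Other splits of the animals into groups of the same sizes (100 drawn of 126) were set against each count of called genes. For 2 d against sham 2 of 100 splits gave at least the real 669, the real one included. The highest other gave 1448 with sham 1 and CVST 2 d animal 5 exchanged. For 7 d against sham 2 of 100 gave at least 752. The highest other gave 1003 with CVST 7 d animal 2 among the sham animals. Both of these splits placed a CVST animal that lay near sham on the first component with sham, which points to a structure of the samples within the groups. For 7 d against 2 d 1 of 100, the real one with 473, was as large. The highest other gave 221. Counts of 1 or 2 in 100 argue against chance without excluding it.

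A sample far from the others of its group was found in 12 of 177 groups tested, where chance gives about 1 in 20, or 8.85. Beyond those given above, lymphocytes in sham 3 scored -0.80 (gap 0.915 of the range) and the p53 list in sham 1 scored 0.17 (0.927). In CVST 2 d, pattern recognition in animal 2 scored 2.21 (0.726), mitochondrially encoded genes in animal 4 -0.59 (0.756) and thalamus in animal 3 -0.16 (0.767). In CVST 7 d, animal 4 was lowest for inhibitory interneurons (-0.66, 0.715) and mitochondrially encoded genes (-0.41, 0.881).

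With all animals in the test, 38 genes named for 7 d against 2 d and given here differed, by these log2 values. Higher at 7 d were H1f4 (2.48), Lag3 (2.45), Fam180a (2.08), Fmod (1.96), Kcne1l (1.91), Ddx60 (1.84), Gpnmb (4.05), Clec7a (3.78), Apoe (1.69), P2ry12 (0.99), Rsad2 (1.64), C2 (1.50), Gja1 (0.93), Slc1a2 (0.74) and Ndrg2 (0.60). Lower at 7 d were Il11 (-4.81), Selp (-4.04), Hba-a1 (-3.60), Fndc9 (-2.74), Hspb1 (-2.47), Socs3 (-2.44), Tnfrsf12a (-2.27), Bdkrb2 (-2.13), Fos (-2.04), Lrg1 (-1.91), Tm4sf1 (-1.87), Cdkn1a (-1.67), Adm (-1.49), Arc (-1.48), Ptgs2 (-1.29), S100a10 (-1.13), Junb (-1.03), Ldha (-0.66), Srxn1 (-0.58), Atf4 (-0.51), Xbp1 (-0.50), Gsr (-0.46) and Aen (-0.41).

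Among 312 tested assembled loci without an Ensembl gene, which the comparisons leave out, 12 were called at 2 d against sham (10 higher and 2 lower), 1 at 7 d against sham (higher), and 2 higher and 7 lower at 7 d against 2 d.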

How the results depend on the processing

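The tests with the choroid plexus or striatal score as a covariate, with the assembled loci kept in, without both animals nearest to sham, and with the exact permutation were chosen only after the result was seen. DESeq2 size factors, a CPM of at least 1 in 4 samples, the robust fit, the removal of mitochondrial and haemoglobin genes, the striatal covariate and the assembled loci kept the counts of higher and lower genes of each comparison within 1.5 times. No setting moved the median log2 fold change of all genes by over 0.1. At group means of 16.7 to 18.5 M counts per library (M for mega) some genes stay out of reach, such as Cd3e with 13 counts over the 14 samples.

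Genes higher and lower than sham at 2 d numbered 1079 and 421 with the DESeq2 Wald test, 1420 and 1196 with voom and sample quality weights, 211 and 35 with log2(FPKM + 1), and 1372 and 774 without both animals nearest to sham. With the replicate block 186 were higher, and with log2(FPKM + 0.1) 61 were lower. At 7 d against sham they numbered 1064 and 323 with the Wald test, 55 and 26 with the block, 232 and 33 with log2(FPKM + 1), 374 and 39 with log2(FPKM + 0.1), and 397 and 65 with the choroid plexus score as a covariate. Lower genes at 7 d were 290 with voom and 92 with no filter on low counts, where more genes were tested, and 1141 were higher without both animals nearest to sham. Between 7 d and 2 d higher and lower genes numbered 641 and 637 with the Wald test, 586 and 651 with voom, 57 and 34 with the block, 128 and 112 with log2(FPKM + 1), 130 and 109 with log2(FPKM + 0.1), 127 and 95 with the choroid plexus covariate, 498 and 415 without both animals nearest to sham, and 55 and 26 with only the 2 groups fitted. The block spends degrees of freedom on a numbering that did not pair the animals: 13 same-number pairs had a median r of -0.045, and 2 of 14 animals were best matched with their own number. For the rest the cause was not tested.

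Genes higher and lower at both times numbered 460 and 81 with the Wald test and 23 and 16 with the block. The early, sustained and late higher classes held 232, 421 and 226 genes with the Wald test and 23, 22 and 7 with the block, and the lower classes 112, 76 and 63, and 12, 16 and 1. The cause was not tested.

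Leaving out 1 animal in turn gave 60 to 1193 higher and 16 to 774 lower genes at 2 d (lowest without sham 3, highest without CVST 2 d animal 5), 101 to 892 and 18 to 143 at 7 d (sham 3; CVST 7 d animal 2), and 98 to 604 and 75 to 705 between the times (CVST 2 d animals 1 and 5). Genes at both times ranged from 12 to 372 higher and 3 to 69 lower, early genes from 20 to 363 and 7 to 259, sustained genes from 12 to 344 and 3 to 66, and late genes from 14 to 154 and 2 to 41. The correlation of the 2 d and 7 d effects ranged from 0.712 to 0.793. The matrix list between 7 d and 2 d ranged from a median of 0.00399 without CVST 7 d animal 5, where camera turned its direction without passing (adjusted p = 0.593), to 0.836 without CVST 7 d animal 1. Of the other list results with 1 animal left out, 970 kept direction and side of the threshold, 43 came to pass and 22 no longer passed. For named genes 1290 kept both, 10 came to pass and 467 no longer passed, where fewer samples were tested.

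Of 111 list results, 49 kept direction and side of the threshold with an estimated correlation (62 no longer passed), 76 with the exact permutation (35), 78 with fry (33), 110 with size factors (1 came to pass), 99 with no filter (12 came to pass) and 103 with the block (6 came to pass, 2 no longer passed). For 191 named gene results the counts were 189 with size factors (2 no longer passed), 182 with the Wald test (7 came to pass, 2 no longer passed), 163 with voom (5 and 23) and 96 with the block (95 no longer passed), and for 185 of them 141 with only the 2 groups fitted (3 and 41). The cause was not tested.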

Other observations

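The lists in this part, and the members named from them, were chosen after their values were seen, and so were their tests, apart from those of the clock and leptomeninges lists. Their p were adjusted over these 7 lists alone, so a pass here is not on the scale of the 37 lists. Where a list was chosen from these same values, its p describes the list and cannot count as support for it.

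The p200 family holds interferon-inducible proteins, some of which bind DNA, and its genes are similar in sequence, so that reads can be shared between members. Of 9 measured members, 2 of which are also in the interferon or pattern recognition lists, 4 were higher at 2 d than in sham (Ifi209 4.17 ± 0.77, Ifi207 4.07 ± 0.91, SE) and 8 at 7 d (Ifi209 5.55 ± 0.75, Ifi207 5.35 ± 0.91, Ifi211 4.59, Ifi204 4.38). Summed counts of Ifi209 were 4 in sham, 101 at 2 d and 252 at 7 d. The list had a median of 1.82 at 2 d (camera adjusted p = 0.000163, adjusted p = 0.206 with an estimated correlation) and 3.98 at 7 d (1.43e-17, and 0.0218 with an estimated correlation), and its score was above sham in 10 of 10 CVST animals (0.87 to 3.22). Between the times Ifi213 (2.73) and Mndal (1.19) were higher at 7 d (median 1.26, camera adjusted p = 1.95e-07, adjusted p = 0.054 with an estimated correlation). The calls at 2 d ended without sham 3 or 4 and numbered 1 without sham 1 or 2, 2, 1 and 1 without CVST 2 d animals 1 to 3. Those at 7 d numbered 5, 4 and 4 without sham 2 to 4 and 5 without CVST 7 d animals 4 or 5, and those between the times 1 without CVST 7 d animal 5.

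Genes of newly formed oligodendrocytes (10 measured, 2 of them shared with the precursor and thalamus lists) had 6 members higher at 7 d than at 2 d: 9630013A20Rik (1.81 ± 0.27), Enpp6 (1.49 ± 0.23), Gpr17 (1.33), Bmp4 (1.14), Tcf7l2 (0.98) and Sirt2 (0.50), with a median of 0.75 (camera adjusted p = 4.3e-11, adjusted p = 0.0246 with an estimated correlation). Scores were -0.43 to -0.15 in the 5 animals at 2 d and 0.15 to 0.85 in the 5 at 7 d. Against sham, Enpp6 (1.42 ± 0.25) and Bmp4 (0.92 ± 0.24) were higher at 7 d (median 0.54, camera adjusted p = 2.5e-05, adjusted p = 0.119 with an estimated correlation), and the list did not pass at 2 d (median -0.16, camera adjusted p = 0.0794). Against sham the number of calls was 1 without sham 2, 3 or 4, CVST 2 d animals 3 or 4, or CVST 7 d animals 2, 4 or 5. Between the times the number was 4 without CVST 2 d animal 1 or CVST 7 d animal 4.

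A list of histone genes held 13 members of the histone clusters and the replacement linker histone H1f0 (-0.0044 at 2 d against sham). At 2 d H2ac6 (-2.19 ± 0.41), H1f4 (-2.02 ± 0.40) and H2bc6 (-1.30 ± 0.29) were lower than in sham among 14 measured (median -0.42, camera adjusted p = 0.00144, adjusted p = 0.206 with an estimated correlation), with scores of -0.72 to -0.36 in all 5 animals. Between the times H1f4 (2.48), H2ac6 (2.22) and H2bc6 (1.19) were higher at 7 d (median 0.84, camera adjusted p = 5.54e-06, adjusted p = 0.0436 with an estimated correlation). At 7 d against sham the list did not pass (0.29, camera adjusted p = 0.409). The 2 d calls ended without sham 2 or 4 and numbered 1 without sham 3.

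The clock output arm was lower as a list at 2 d than in sham (median -0.27, camera adjusted p = 0.0063, adjusted p = 0.206 with an estimated correlation), with no member called (lowest adjusted p = 0.0507, for Dbp), and higher at 7 d than at 2 d (median 0.46, camera adjusted p = 5.54e-06, adjusted p = 0.0351 with an estimated correlation; 2 members called, Dbp 0.78 and Nr1d2 0.40). Those calls ended without CVST 2 d animal 1 and numbered 1 without sham 2 or 3, CVST 2 d animals 2 to 4 or any CVST 7 d animal. The positive arm did not pass in any comparison (camera adjusted p = 0.604 at 2 d, 0.294 at 7 d and 0.534 between the times). The glucocorticoid response list did not pass either (0.0904, 0.0731 and 0.839), and CVST 2 d animal 5 scored 1.33 where the other 2 d animals scored -0.13 to 0.11. Resting leptomeninges did not pass at 2 d (0.111) or 7 d (0.409) and was higher at 7 d than at 2 d (0.0117, adjusted p = 0.301 with an estimated correlation; 3 members higher and 1 lower). No higher member was called without CVST 2 d animals 3 or 4 or CVST 7 d animal 3, and 1 without CVST 2 d animal 1 or CVST 7 d animal 4.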
